A study of Homo sapiens with 6 samples.

How the data were processed

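Gene expression was measured in A549 cells, an established human lung adenocarcinoma line, 24 h after transfection with a synthetic mimic of the microRNA miR-608, a mimic of miR-552-3p or a negative control mimic. Each of the 3 groups has 2 arrays, 6 arrays in all. Per the labels' protocols, total RNA was purified on columns, amplified and labelled with biotin, and hybridised to Illumina bead arrays. Nothing in the labels says that the 2 arrays of a group came from separate cultures. The p-values thus measure at most the spread between these samples, which may be technical.

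The authors deposited a table of the average signal intensity of 47319 probes per array on a linear scale, made with GenomeStudio 2011.1 per the submitters' processing notes. The deposited table also gives a detection p-value per probe and array, per the file headers, which ranks the probe against 770 negative control probes. Whether background was subtracted is not given in the sources used here. The lowest signal on every array was positive, between 61.77 and 77.53, and the inferred background mean lay between 150.7 and 168.2. These values argue against a subtraction. The authors also deposited log2 values of 17751 probes. Set against the signals, these are log2 signals after quantile normalization over the probes with a detection p under 0.05 on at least 4 of the 6 arrays, with a largest gap of 0.00029 and 0 differences in order. They are not centred, their direction is that of the signals and their median is 9.53 on every array; the method itself is not given in the sources used here.

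The signals were corrected for background, offset by 16, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), with the negative control distribution inferred from the detection p-values. Probes with a detection p under 0.05 on at least 2 arrays were kept, which left 20749 and removed 26570. Of all probes, 30112 had 1 gene symbol in the platform annotation, 8 had several and 17199 were not listed and are unnamed here. Gene identifiers of 30073 probes matched the RefSeq gene table of GRCh38.p14, used only for names and for which genes lie within which, 39 did not, and 0 symbols changed. A gene was represented by its kept probe with the highest mean, and unnamed probes were kept on their own, which gave 16891 rows, 11817 named genes and 5074 unnamed probes. Of the named genes 3080 had several kept probes, and where another probe of a named gene was called in the opposite direction this is stated. No coordinates are printed because no genome build is given in the sources used here.

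The arrays differed little in brightness. The median signal lay between 181.7 and 200.7, the inferred background mean between 150.7 and 168.2, and 18550 to 19758 probes were detected per array. The number of arrays limits the precision.

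One linear model over all 6 arrays was fitted with limma (lmFit and eBayes, 3 residual and 5.12 total degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05 with no minimum fold. Fold changes are on the log2 scale after the offset, which understates changes of dim probes. Where every array of a group had a detection p of 0.05 or more, the fold is given as a bound, from the bright group's mean against the higher of the lowest detected value and the probe's own value on each array of the dim group. The 20 gene lists, the designs, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 19 lists with at least 2 measured members, with camera at an estimated correlation and fry beside it. At the preset correlation camera compares a set of genes with the other rows, so its p-values do not measure the spread between arrays. Camera with an estimated correlation works with the 3 residual degrees of freedom of the fit, so its p-values can stay high whatever the correlation is. Fry tests whether the genes of a list move on balance one way, without comparing them with other genes. The rule named, against the control, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, 5 each way between the mimics, up to 4 members of each list with the smallest p, every member of the lists of published targets, and 5 shared genes each way. A part of the rule on genes with seed sites, and the planned comparison of genes with and without seed matches in their 3' untranslated regions, were not run because no transcript sequences were used here. Some genes of the fixed lists are not reported here.

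The steps were tested on simulated data made from the real signals, for miR-608 against control. A simulation that drew the background anew on each array recovered 0 of the changed genes, among 200 changed and 31448 rows. Undetected probes showed a background SD of 22.1 between probes and 14.5 within a probe, so that simulation had probably overstated the noise. It was replaced after its result was seen by one with these values. Undetected probes leave out the bright end of the background, so both values may be too low and the recovery below too high. The inferred background SD of an array was 33.36 to 37.19. The replacement also gave no signal to probes that the detection filter had removed, and drew the spread of the signal from the fit to bright probes. The share of each change in the better recovery was not tested. With 200 genes changed among 21825 rows, the replacement recovered 83.3% of changes of log2 2, 57.6% of log2 1 and 1.56% of log2 0.5, and 6.93% of the calls were false. With 6225 genes changed among 21731 rows it recovered 95.9%, 87.4% and 63.6% at these sizes, and 6.58% of the calls were false, above the nominal level. Alternatives covered the background correction, the normalization, the detection filter, the choice of probe, the moderation, the arrays in the fit, a replicate block, each array left out in turn and a minimum fold.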

Results

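The data are expression profiles of A549 lung adenocarcinoma cells 24 h after transfection with a negative control mimic, a miR-608 mimic or a miR-552-3p mimic, with 2 arrays in each group. According to the series title, the study asked which genes each microRNA silences. Arrays of the same group correlated at 0.994 (Pearson, across probes, which are not independent replicates) and arrays of different groups at 0.969 to 0.979. The median SD between the arrays of a group was 0.0865 log2 units in the control, 0.0838 with miR-608 and 0.0832 with miR-552-3p. Values are log2 fold changes ± SE from limma with 2 arrays per group.

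With miR-608, the pro-apoptotic gene BIK rose most among genes detected in the control, by 3.22 ± 0.08 or 9.31-fold (adjusted p = 0.00135). The cytokine IL32 rose by 2.51 ± 0.12, the LIM domain protein PDLIM7 by 2.33 ± 0.08, urokinase (PLAU) by 2.10 ± 0.09 and the AP-1 subunit FOSL1 by 2.05 ± 0.10, and C3orf52 and CRMP1 rose by 2.07 and 1.90. Of the 2 other PDLIM7 probes 1 was not called. Against a control below detection, the interferon-induced IFI27 was at least 4.19-fold higher, REPS2 at least 3.47-fold and the GTPase RRAD at least 2.61-fold. Among the largest falls were those of TRMT2B (-2.48 ± 0.47), SAMD4B (-2.40 ± 0.09), the deiodinase DIO2 (-2.29 ± 0.15), the transcription factor SOX21 (-2.29 ± 0.10), the reductase CYB5R3 (-2.24 ± 0.07) and the small GTPase ARF3 (-2.20 ± 0.11). FOXM1, a transcription factor of proliferating cells, fell by 2.16 ± 0.08, the clathrin adaptor AP2B1 by 2.09 ± 0.08 and the mitotic gene CDCA3 by 2.08 ± 0.11, and FCHO1 dropped below detection, at least 4.80-fold lower. TRMT2B did not pass without control replicate 1 (adjusted p = 0.0864) or control replicate 2 (adjusted p = 0.0767).

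In all, 4941 of 16891 rows, which are named genes and unnamed probes, differed between miR-608 and control, 2410 higher and 2531 lower. Among the 810 that changed at least 2-fold, 508 or 62.7% were lower. The arrays of the groups did not overlap for 11116 rows, or 65.8%, where chance gives 33.3%. The count was 2382 without control replicate 1, 2499 without control replicate 2, 2580 without miR-608 replicate 1 and 2483 without miR-608 replicate 2, and 2981 with no detection filter.

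Of 19 measured interferon-stimulated genes, 10 rose and 1 fell with miR-608 (adjusted over the list alone, 10 and 2), among them MX1 (1.88 ± 0.10), ISG15 (1.54 ± 0.08) and IFI6 (1.34 ± 0.08). Of 13 NF-kB target and cytokine genes 7 rose and 0 fell (10 and 0 over the list alone), including the chemokines CCL20 (1.82 ± 0.07), CXCL5 (1.63 ± 0.09) and CXCL8 (1.57 ± 0.08) and the NF-kB subunit RELB (0.99 ± 0.11). Of 14 cholesterol synthesis genes 9 rose and 0 fell (9 and 0 over the list alone). The rises included INSIG1 (1.06 ± 0.07), MSMO1 (1.06 ± 0.08), HMGCS1 (0.89 ± 0.10) and SQLE (0.56 ± 0.07). Of the 2 other MSMO1 probes 1 was not called, at 0.08. Each of these lists shifted upward (camera, adjusted p = 0.000327), but did not pass with an estimated correlation (adjusted p = 0.147 for each). Hypoxia and glycolysis genes shifted upward, with 6 higher and 1 lower of 15 (7 and 1 over the list alone; adjusted p = 0.0199, or adjusted p = 0.386 with an estimated correlation), among them ANKRD37 (1.24 ± 0.13) and the glucose transporter SLC2A1 (0.78 ± 0.08), while PFKFB3 fell by 0.70 ± 0.08. TGF-beta target genes shifted upward, with 6 higher and 2 lower of 14 (7 and 2 over the list alone; adjusted p = 0.0355, or adjusted p = 0.324 with an estimated correlation). In that list CCN2 (1.60 ± 0.09) and TAGLN (1.55 ± 0.09) rose and ID3 fell by 1.12 ± 0.08, and the shift did not pass without control replicate 2 (adjusted p = 0.0618) or without miR-608 replicate 1 (adjusted p = 0.0732), nor with detection required on all arrays (adjusted p = 0.0619).

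Neither cell cycle list passed with miR-608. Of 23 G1/S and replication genes 10 fell and 2 rose, including E2F2 (-1.17 ± 0.10), CDK6 (-0.90 ± 0.10) and cyclin CCND3 (-0.67 ± 0.08). Of 22 mitotic genes 8 fell and 2 rose, including KIF20A (-0.99 ± 0.08). The adjusted p was 0.0606 for each list, and both passed with no background correction (adjusted p = 0.0427), with normexp (adjusted p = 0.048), with no detection filter (adjusted p = 0.0117) and with an intensity trend (adjusted p = 0.0153 and 0.019). Of 5 measured genes published elsewhere as miR-608 targets, 2 fell, the anti-apoptotic BCL2L1 (-1.10 ± 0.08) and the growth factor receptor EGFR (-0.94 ± 0.08). A second EGFR probe was called in the opposite direction, at 0.50. CD44 was at -0.21 ± 0.07 (adjusted p = 0.0868), CDC42 at -0.10 ± 0.14 (adjusted p = 0.665) and MIF at 0.14 ± 0.07 (adjusted p = 0.178), and none of these passed. Of the 2 other CD44 probes 1 was called at -0.56 and 1 was not, at -0.18. CD44 passed with the authors' values (adjusted p = 0.0351), with detection on all arrays (0.0402) and with an intensity trend (0.00594), and MIF with an intensity trend (0.044). Another CDC42 probe was called at 0.52, and CDC42 was at 0.022 without control replicate 1 and 0.052 without miR-608 replicate 2. The list as a whole did not pass (adjusted p = 0.118). Members of the microRNA machinery went both ways, with TNRC6A (1.24 ± 0.07) and AGO2 (0.78 ± 0.11) higher and DROSHA (-0.55 ± 0.08) lower. DROSHA did not pass without control replicate 2 (adjusted p = 0.0534), miR-608 replicate 1 (adjusted p = 0.0527) or miR-608 replicate 2 (adjusted p = 0.0511). The remaining lists did not pass, with 3 higher and 1 lower of 17 p53 target genes (adjusted p = 0.977), 5 and 3 of 19 apoptosis regulators (adjusted p = 0.534), 2 and 0 of 9 mesenchymal markers (adjusted p = 0.547), and 3 and 2 of 12 epithelial markers (adjusted p = 0.889). Higher and lower were 3 and 3 of 18 NRF2 targets (adjusted p = 0.558), 4 and 4 of 18 genes of the unfolded protein response (adjusted p = 0.69), 4 and 1 of 18 growth factor signalling genes (adjusted p = 0.21) and 4 and 1 of 11 genes of the microRNA machinery (adjusted p = 0.21). The p53 target list had a median of -0.06 and a mean of 0.02. Markers of other cell types did not pass as lists (adjusted p = 0.534 for alveolar type II, 0.558 for fibroblast and endothelial and 0.534 for immune markers).

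With miR-552-3p, FOSL1 rose most among genes detected in the control, by 3.55 ± 0.10 or 11.7-fold (adjusted p = 0.000911). Against a control below detection, the aldehyde oxidase AOX1 was at least 7.10-fold higher, CGB5 at least 5.26-fold and RRAD at least 4.81-fold; CGB5 has near-identical copies that its probe may not separate. The U4 spliceosomal RNAs RNU4-1 (3.25 ± 0.32) and RNU4-2 (2.74 ± 0.35), themselves near-identical and so uncertain one by one, rose, as did GLIPR1 (2.71 ± 0.08), the transcription factor CREB5 (2.59 ± 0.09), the cytokine IL11 (2.45 ± 0.23) and MARCHF4 (2.41 ± 0.08). Among the largest falls were those of the phosphatase CTDSPL (-2.84 ± 0.10), EI24 (-2.56 ± 0.11), C9orf40 (-2.47 ± 0.12), the histone methyltransferase subunit RBBP5 (-2.46 ± 0.08) and CEMIP (-2.33 ± 0.11). EFHD1 dropped below detection, at least 6.58-fold lower, as did the kinase MAP2K6, at least 4.19-fold, and NFE2, at least 2.73-fold. The receptor FGFR3 was at -2.63 ± 0.25 and detected on 1 of 2 miR-552-3p arrays, and its other probe, at -0.39, was not called. The probe annotated to the pseudogene RNF4BP was at -2.38 ± 0.12 and may read its parent gene.

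In all, 5308 of 16891 rows differed between miR-552-3p and control, 2469 higher and 2839 lower. Of the 1007 that changed at least 2-fold, 651 or 64.6% were lower. The arrays did not overlap for 11306 rows, or 66.9%, where chance gives 33.3%. The count was 2923 without control replicate 1, 3032 without control replicate 2, 2917 without miR-552-3p replicate 1 and 3131 without miR-552-3p replicate 2, and 3377 with no detection filter.

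With miR-552-3p, 13 of 23 G1/S and replication genes fell and 0 rose (16 lower and 1 higher adjusted over the list alone), including E2F2 (-1.65 ± 0.10), CCND3 (-1.60 ± 0.08), CDK6 (-0.95 ± 0.10) and CDC45 (-0.68 ± 0.08). Of 17 p53 target genes, many of which act in growth arrest and DNA repair, 12 rose and 0 fell (13 and 0 over the list alone), including SESN1 (1.89 ± 0.11), TIGAR (1.16 ± 0.12), MDM2 (0.98 ± 0.09) and the cell cycle inhibitor CDKN1A (0.90 ± 0.07). Both shifts had an adjusted p of 7.32e-05 with camera, or adjusted p = 0.162 with an estimated correlation. Hypoxia and glycolysis genes shifted upward, with 8 higher and 1 lower of 15 (9 and 1 over the list alone; adjusted p = 0.00737, or adjusted p = 0.25 with an estimated correlation), among them SLC2A1 (0.64 ± 0.08) and the hexokinase HK2 (1.17 ± 0.19), which did not pass without miR-552-3p replicate 1 (adjusted p = 0.0506) or 2 (adjusted p = 0.0532). Of 22 mitotic genes 6 fell and 0 rose (adjusted p = 0.0584), including the survivin gene BIRC5 (-1.89 ± 0.10) and CENPF (-1.07 ± 0.11). Of 19 apoptosis regulators 5 rose and 3 fell (6 and 3 over the list alone), and the list did not pass (adjusted p = 0.449). The pro-apoptotic BIK (1.82 ± 0.08), PMAIP1 (0.99 ± 0.13) and BAX (0.95 ± 0.09, with its other probe at 0.37 and not called) rose, as did the anti-apoptotic BCL2L1 (0.46 ± 0.08). The falls were those of the pro-apoptotic DIABLO (-0.68 ± 0.08, with 1 of its 2 other probes not called) and, named after their values were seen, of the caspase CASP9 (-0.68 ± 0.11) and the anti-apoptotic MCL1 (-0.40 ± 0.10). The other CASP9 probe, at -0.52, was not called, and the other MCL1 probe was called in the opposite direction, at 0.79. CASP9 did not pass without either control array or miR-552-3p replicate 1 (adjusted p of 0.0504 to 0.0555). MCL1 did not pass when any 1 array was left out (adjusted p of 0.0549 to 0.151), with no detection filter (adjusted p = 0.107), with a replicate block (adjusted p = 0.0699) or with only the groups compared (adjusted p = 0.0549).

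Interferon-stimulated genes shifted downward with miR-552-3p, with 8 lower and 1 higher of 19 (9 and 1 over the list alone). IFIT1 fell by 2.00 ± 0.10, IRF9 by 0.69 ± 0.07 and HERC5 by 0.61 ± 0.08, and MX1 dropped below detection, at least 1.62-fold lower. NF-kB targets shifted upward, with 5 higher and 1 lower of 13 (7 and 2 over the list alone), and here CXCL8 (1.84 ± 0.08), NFKB2 (1.40 ± 0.10) and CXCL5 (1.37 ± 0.09) rose while PTGS2 fell by 1.19 ± 0.07. Mesenchymal markers shifted upward by a mean of 0.50, with 3 higher and 1 lower of 9 (3 and 1 over the list alone), led by TNC (1.17 ± 0.08) and SNAI2 (1.71 ± 0.22, detected on 1 of 2 control arrays), whose other probe, at 0.74, was not called. These 3 shifts had an adjusted p of 0.0435, or adjusted p = 0.25 with an estimated correlation. The interferon shift did not pass without control replicate 1 (adjusted p = 0.0635), miR-552-3p replicate 2 (adjusted p = 0.058) or either miR-608 array (adjusted p = 0.0534). The NF-kB shift did not pass without control replicate 1 (adjusted p = 0.0693) or those same other arrays. The mesenchymal shift did not pass without control replicate 1 (adjusted p = 0.0635), control replicate 2 (adjusted p = 0.0692) or miR-552-3p replicate 2 (adjusted p = 0.058). With the authors' log2 values the mesenchymal mean was 0.28 (adjusted p = 0.0586), and with detection required on all arrays 0.29 (adjusted p = 0.137). The interferon shift did not pass with the authors' values (adjusted p = 0.0586), with detection on all arrays (adjusted p = 0.133) or with only the groups compared in the fit (adjusted p = 0.0534). The NF-kB shift did not pass with detection on all arrays (adjusted p = 0.0967) or with only the groups compared (adjusted p = 0.0534).

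Genes published elsewhere as miR-608 targets shifted upward with miR-552-3p, with EGFR (1.14 ± 0.08) and BCL2L1 (0.46 ± 0.08) higher and 0 lower of 5 (2 and 0 over the list alone; adjusted p = 0.0331, or adjusted p = 0.25 with an estimated correlation). The shift did not pass without miR-552-3p replicate 2 (adjusted p = 0.058) or with detection required on all arrays (adjusted p = 0.0589). BCL2L1 did not pass without control replicate 1 (adjusted p = 0.0556), miR-552-3p replicate 1 (adjusted p = 0.0567) or miR-552-3p replicate 2 (adjusted p = 0.0518). CDC42 (0.39), MIF (0.18) and CD44 (0.17) did not pass, but the other CDC42 probe was called at 1.15. CDC42 passed with the authors' values (adjusted p = 0.0273), with no background correction (0.0442), with detection on all arrays (0.0473) and with an intensity trend (0.00648), and MIF and CD44 passed with an intensity trend (0.0146 and 0.0234). Of the genes published elsewhere as miR-552 targets only RUNX3 was measured here; it fell with miR-552-3p (-1.53 ± 0.15) and with miR-608 (-1.24 ± 0.15). The remaining lists did not pass, with 6 higher and 3 lower of 14 TGF-beta targets (adjusted p = 0.0584), and 8 and 1 of 14 cholesterol synthesis genes (adjusted p = 0.0584). Higher and lower were 2 and 4 of 12 epithelial markers, 3 and 6 of 18 NRF2 targets and 2 and 4 of 11 genes of the microRNA machinery (adjusted p = 0.668 for each). Higher and lower were 1 and 6 of 18 genes of the unfolded protein response and 3 and 9 of 18 growth factor signalling genes (adjusted p = 0.0819 for each). Epithelial markers had a median of 0.03 and a mean of -0.07, and NRF2 targets a median of -0.02 and a mean of 0.004 with a downward test. Markers of other cell types did not pass as lists (adjusted p = 0.668 for alveolar type II, 0.391 for fibroblast and endothelial and 0.758 for immune markers).

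**Figure D1:**
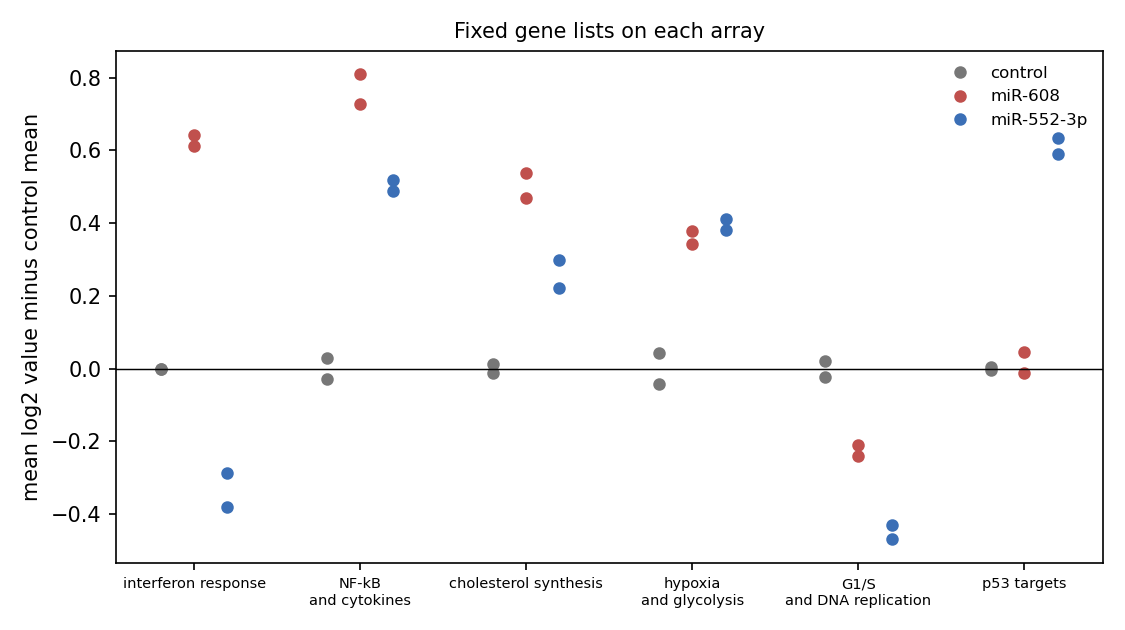
Mean log2 value of the measured members of 6 gene lists on each of the 6 arrays, minus the mean of the control arrays; each point is 1 array, coloured by group. For interferon-stimulated genes the miR-608 arrays lie at 0.643 and 0.613 and the miR-552-3p arrays at -0.287 and -0.382.

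Set directly against each other, the mimics differed in 6266 rows, 3194 higher and 3072 lower with miR-608. The arrays did not overlap for 11720 rows, or 69.4%, where chance gives 33.3%. The count was 4158 without miR-608 replicate 1, 4173 without miR-608 replicate 2 and 4128 without miR-552-3p replicate 1. Higher with miR-608 were the translation repressor EIF4EBP2 (3.51 ± 0.19, detected on 1 of 2 miR-552-3p arrays), SCML2 (2.98 ± 0.15) and FGFR3 (3.11 ± 0.25, with its other probe at 0.18 and not called), and GPR162 and MX1 were at least 6.74-fold and 5.99-fold higher. Lower with miR-608 were DIO2 (-3.09 ± 0.15), RNU4-1 (-2.84 ± 0.32) and TLNRD1 (-2.74 ± 0.07), and AOX1 and the serotonin receptor HTR2B were at least 6.92-fold and 6.05-fold lower. Interferon-stimulated genes were higher as a list with miR-608, 11 of 19 with 1 lower (12 and 1 over the list alone; adjusted p = 0.000181, or adjusted p = 0.196 with an estimated correlation), with IFIT1 at 2.72 ± 0.10 and IFI6 at 1.76 ± 0.08. The p53 target genes were lower as a list, 12 of 17 with 1 higher (12 and 1 over the list alone; adjusted p = 0.00029, or adjusted p = 0.196 with an estimated correlation), with CDKN1A at -1.46 ± 0.07 and SESN1 at -1.66 ± 0.11. Published miR-608 targets were lower, 3 of 5 with 0 higher (4 and 0 over the list alone; adjusted p = 0.0219, or adjusted p = 0.32 with an estimated correlation), with EGFR at -2.07 ± 0.08, BCL2L1 at -1.57 ± 0.08 and CD44 at -0.38 (adjusted p = 0.0135). CD44 did not pass without either miR-608 array or either miR-552-3p array (adjusted p of 0.0511 to 0.0686) or with no detection filter (adjusted p = 0.0577), and of its 2 other probes 1 was called at -0.57 and 1 was not, at -0.41. CDC42 (-0.48), MIF (-0.03) and, of the published miR-552 targets, RUNX3 (0.29) did not pass. The other CDC42 probe was called at -0.64, and CDC42 passed with the authors' values, no background correction, normexp, median scaling, detection on all arrays and an intensity trend (adjusted p of 0.00107 to 0.0476). RUNX3 passed with an intensity trend (adjusted p = 0.037). Growth factor signalling genes were higher, 10 of 18 with 2 lower (10 and 3 over the list alone; adjusted p = 0.043, or adjusted p = 0.32 with an estimated correlation), with MAPK3 at 1.34 ± 0.10 and MAP2K1 at 1.33 ± 0.11. That shift did not pass when any 1 array was left out (adjusted p of 0.052 to 0.0732), with the authors' values (adjusted p = 0.0699), with detection on all arrays (adjusted p = 0.0585) or with only the groups compared (adjusted p = 0.052).

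The other lists did not pass between the mimics, with adjusted p = 0.0863 for G1/S genes, 0.971 for mitosis, apoptosis regulators, epithelial markers, hypoxia and immune markers, 0.394 for NF-kB targets and 0.221 for mesenchymal markers. The adjusted p was 0.805 for TGF-beta targets and alveolar type II markers, 0.561 for NRF2 targets, 0.116 for the unfolded protein response, 0.117 for cholesterol synthesis, 0.121 for the microRNA machinery and 0.242 for fibroblast and endothelial markers. The median and mean differed in sign for mitosis (-0.07 and 0.04), epithelial markers (-0.17 and 0.01), hypoxia (0.01 and -0.04) and alveolar markers (-0.12 and 0.11), and the immune markers had a negative median and mean with an upward test. No list call in any comparison held with an estimated correlation, a test limited by the 3 residual degrees of freedom. With miR-608 the estimates were -0.0065 for interferon, -0.05 for NF-kB and -0.036 for cholesterol genes, below the preset 0.01. For hypoxia genes the estimate was 0.13. For the lists below the preset value, the lost calls thus do not show that correlation between genes explains the shifts. With fry, the called lists had an adjusted p of 0.000363 to 0.00633 for miR-608, 0.00065 to 0.00541 for miR-552-3p and 0.000411 to 0.00152 between the mimics. Most lists that camera did not call also passed with fry, so fry does not set the called lists apart. With miR-608 the fry adjusted p was 0.00212 for NRF2 targets and 0.0318 for immune markers, though 0.672 for p53 targets. It was 0.00158 for epithelial markers with miR-552-3p and 0.000835 for NF-kB targets between the mimics.

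Many genes changed alike with both mimics. Against the control, 918 rows rose with both and 985 fell with both, where independent lists of these sizes share 352.3 and 425.4, and 580 changed in opposite directions. FOSL1, C3orf52, PDLIM7, BIK and RRAD led the shared rises. In each comparison 1 of the 2 other PDLIM7 probes was not called. FOS, NAV1, CPLX2, IQGAP2 and the thioesterase ACOT11 led the shared falls, with FOS at -1.71 ± 0.23 with miR-608 and -2.15 ± 0.23 with miR-552-3p; the other ACOT11 probe was not called in either comparison. IQGAP2 was detected on 1 of 2 arrays with each mimic. ACOT11 did not pass without control replicate 1 (adjusted p = 0.0662 with miR-608 and 0.0564 with miR-552-3p) or control replicate 2 (0.0586 and 0.0501), nor with miR-552-3p without its replicate 1 (0.0507). NAV1 did not pass with miR-552-3p without control replicate 1 (adjusted p = 0.0589). The shared calls numbered 780 without control replicate 1, 818 without control replicate 2, 1049 and 1014 without miR-608 replicate 1 and 2, 1083 and 1123 without miR-552-3p replicate 1 and 2, and 922 with no detection filter. The comparisons share their 2 control arrays. The covariance of their log2 fold changes across rows was 0.0773, against a mean of 0.013 in 100 simulated pairs of unchanged groups that shared the controls. Measures free of the size of the changes lay below those of the unchanged groups: a Pearson correlation of 0.320 (simulated 0.478 to 0.527), a Spearman correlation of 0.327 (0.448 to 0.482) and 61.9% of rows with the same sign (65.6% to 67.4%). With shared controls these measures do not decide whether changes are shared, since changes particular to 1 mimic lower them and unchanged groups have none. With a different control array for each mimic, a test chosen after the data were seen, the covariance was 0.0593 and 0.0613 in the 2 possible assignments, against at most 0.00171 in simulated groups. The Pearson correlation was then 0.229 and 0.239, against -0.0262 to 0.0427 in simulated groups.

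**Figure D2:**
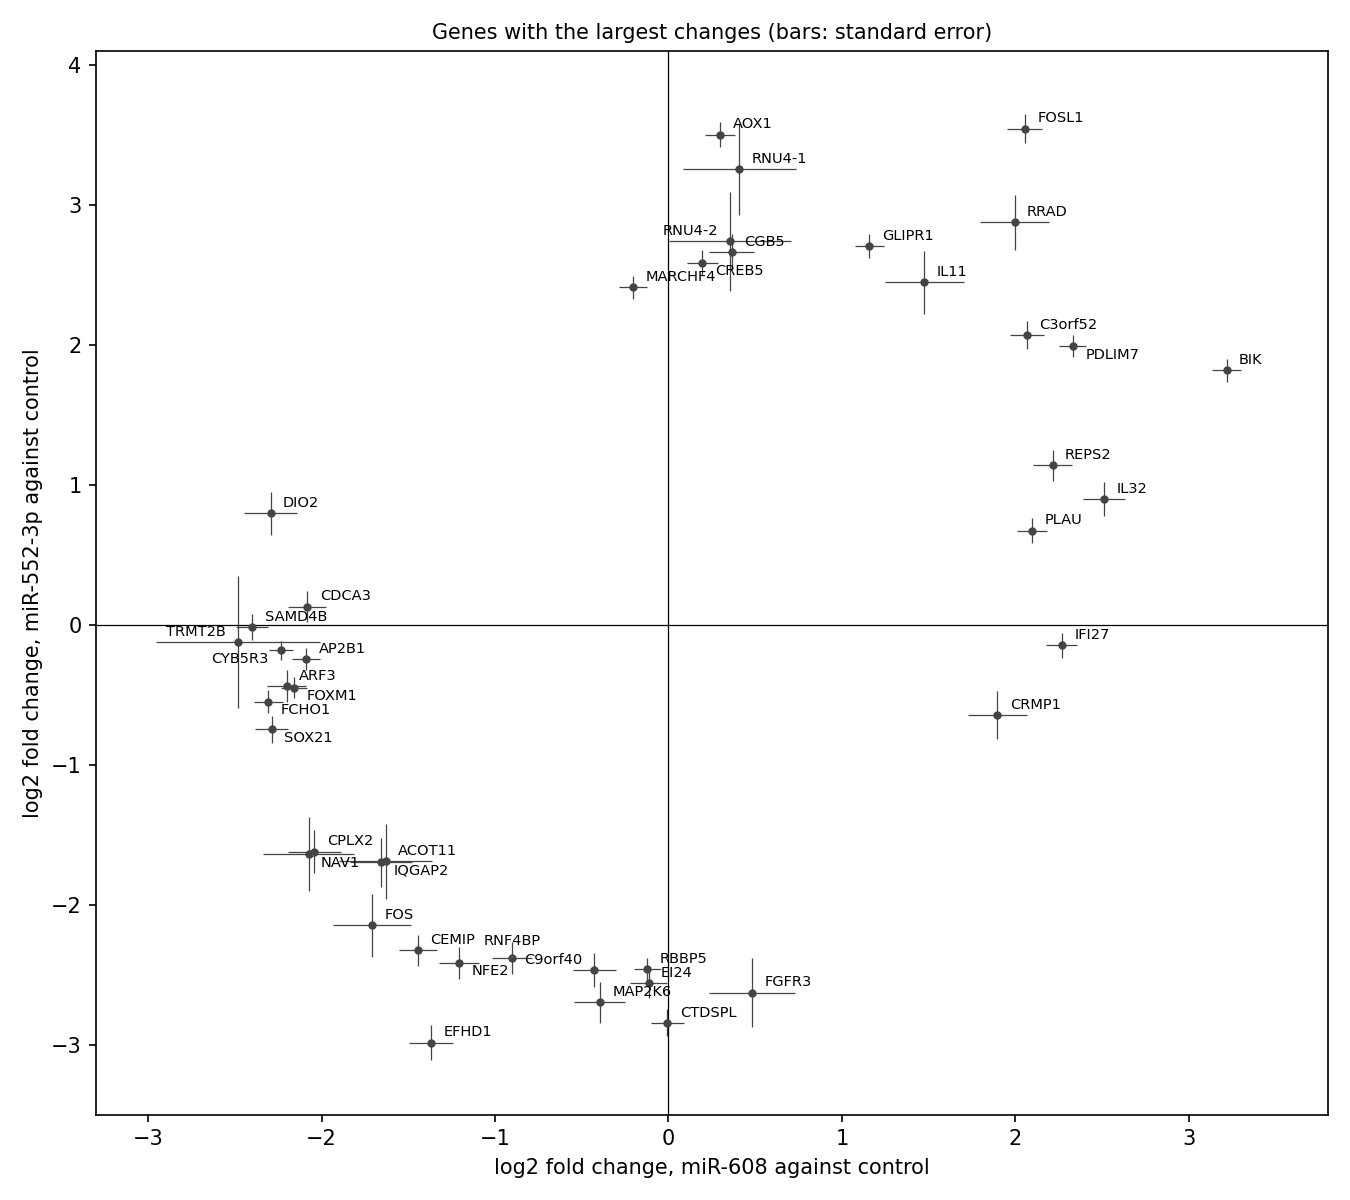
Log2 fold change with miR-608 (horizontal axis) and with miR-552-3p (vertical axis), each against control, for the 43 genes named for the largest or shared changes; bars are standard errors. FOSL1 lies at 2.05 and 3.55, and BIK at 3.22 and 1.82; values of genes below detection in a group are fitted values, not bounds.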

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

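The alternatives in this part were planned, and the seed site comparisons with their alternatives were not run because no transcript sequences were used here. Counts of differing genes in this part are counts of rows, named genes and unnamed probes alike. Without a detection filter the count was 2981 for miR-608 against control, 3377 for miR-552-3p against control and 922 for calls shared by the mimics, as more rows were tested. A minimum fold of 2 left 810, 1007 and 1391 in the 3 comparisons. Leaving out each array in turn, which leaves a lone array assumed to vary like the other groups, gave 2382 to 4172, 2917 to 4593 and 4128 to 5636 differing genes and 780 to 1123 shared calls. Arrays with the same replicate number showed no shared deviation (correlations of deviations -0.0229, 0.0281 and 0.000384 between groups). This does not tell whether they were handled as pairs. A replicate block gave 4145, 4570 and 5575 genes and 1483 shared calls, with no list call changed.

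Called lists lost their call in 32 of 256 values and reversed in 0. Lists that had not passed gained a call in 32 of 653 values and reversed in 24. With miR-552-3p, TGF-beta targets passed under 5 settings (adjusted p of 0.0158 to 0.0475), cholesterol synthesis under 5 (0.0209 to 0.0475), mitosis under 4 (0.0158 to 0.0475), the unfolded protein response under 2 (0.0231 and 0.0387) and growth factor signalling with no detection filter (0.0314). With miR-608, G1/S genes and mitosis each passed under 4 (0.0117 to 0.048) and published targets under 2 (0.0302 and 0.0467). Between the mimics, 5 lists passed with no detection filter: cholesterol synthesis, G1/S genes, mesenchymal markers, the microRNA machinery and the unfolded protein response (0.0265 to 0.0338). For miR-552-3p against control, the interferon list had a mean log2 fold change of -0.255 with the authors' log2 values, -0.304 with detection on all arrays and -0.334 with only the groups compared; mesenchymal markers, at 0.502 as reported, were at 0.279 and 0.285 with the first 2 of these settings; NF-kB targets 0.535 with detection on all arrays and 0.503 with only the groups compared; and published miR-608 targets 0.466 with detection on all arrays. TGF-beta targets with miR-608 were at 0.368 with detection on all arrays. Growth factor signalling between the mimics was at 0.23 with the authors' values, 0.3 with detection on all arrays and 0.301 with only the groups compared. The cause was not tested. With arrays left out, means for miR-552-3p ranged from -0.473 to -0.428 (G1/S), 0.589 to 0.633 (p53 targets), 0.356 to 0.439 (hypoxia), -0.382 to -0.287 (interferon), 0.475 to 0.531 (NF-kB), 0.486 to 0.518 (mesenchymal) and 0.435 to 0.497 (published targets); for miR-608 from 0.613 to 0.643 (interferon), 0.726 to 0.809 (NF-kB), 0.469 to 0.538 (cholesterol), 0.318 to 0.401 (hypoxia) and 0.335 to 0.401 (TGF-beta); and between the mimics from 0.915 to 1.01 (interferon), -0.621 to -0.566 (p53 targets), -0.944 to -0.868 (published targets) and 0.262 to 0.339 (growth factor signalling).

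Reversed values came from lists and genes that were not called, near 0 or near background, and the cause was not tested. NRF2 targets with miR-552-3p were at -0.00406 with the authors' values and with no background correction, -0.0021 with normexp, -0.0219 with cyclic loess and -0.00132 with no detection filter. With no detection filter, alveolar markers with miR-552-3p were at -0.0221, immune markers at 0.044 with miR-552-3p and 0.00981 with miR-608, and mesenchymal markers with miR-608 at -0.016. With median scaling, p53 targets were at -0.0227 and the unfolded protein response at -0.0072 with miR-608, and epithelial markers at -0.0358, mitosis at -0.00606 and TGF-beta targets at -0.0246 between the mimics. Between the mimics apoptosis regulators were at 0.0151 with cyclic loess and immune markers at 0.0222 with detection on all arrays. With arrays left out in turn, ranges that span 0 were -0.000318 to 0.00832 for NRF2 targets, -0.576 to 0.378 for MS4A1, -0.248 to 0.469 for SLC34A2 and -0.257 to 0.117 for TEK with miR-552-3p; -0.0108 to 0.0446 for p53 targets, -0.0142 to 0.0594 for the unfolded protein response, -0.244 to 0.052 for CDC42, -0.691 to 0.263 for MS4A1 and -0.627 to 0.09 for SLC34A2 with miR-608; and -0.0554 to 0.0466 for apoptosis regulators, -0.00624 to 0.0172 for epithelial markers, -0.132 to 0.0856 for immune markers, -0.088 to 0.446 for COL1A2, -0.568 to 0.339 for MS4A1 and -0.025 to 0.349 for TEK between the mimics.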

Other observations

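The gene families and the tests of explanations in this part were chosen after the values were seen, while the interferon list and its values under the other normalizations were planned. In all, 21 families defined by gene symbol or annotation were looked at, and adjusted p-values count all of them. Small nucleolar RNAs, which guide the modification of ribosomal RNA, differed between the mimics: of 96 measured, 25 fell and 5 rose with miR-608 (median -0.34, camera adjusted p = 0.00224, or adjusted p = 0.388 with an estimated correlation), while 31 rose and 3 fell with miR-552-3p (median 0.36, adjusted p = 1.97e-05, or adjusted p = 0.263 with an estimated correlation). Directly compared, 55 were lower with miR-608 and 1 higher (median -0.74, adjusted p = 2.43e-10, or adjusted p = 0.106 with an estimated correlation). The directions were kept under each of the 5 other background corrections or normalizations, but the medians were smaller under some. They ranged from -0.374 to -0.19 with miR-608, 0.205 to 0.347 with miR-552-3p and -0.735 to -0.399 between the mimics. The values nearest 0 came with no background correction. Spliceosomal RNAs rose with miR-552-3p, 8 of 10 with 0 lower (median 1.15, adjusted p = 5.72e-05, or adjusted p = 0.33 with an estimated correlation), but with miR-608 they did not pass (median 0.30, adjusted p = 0.0765). The miR-608 arrays differed here, with medians of 0.101 on replicate 1 and 0.397 on replicate 2. Directly compared, 8 were lower with miR-608 and 1 higher (median -0.91, adjusted p = 0.00179, or adjusted p = 0.253 with an estimated correlation); several of them are near-identical copies. Tubulin genes were higher with miR-608 than with miR-552-3p, 6 of 17 with 0 lower (median 0.23, and 0.108 to 0.25 under the other normalizations; adjusted p = 0.00882, or adjusted p = 0.201 with an estimated correlation). Relative to the control mean, their medians were 0.177 and -0.012 on the miR-608 arrays and -0.18 and -0.167 on the miR-552-3p arrays.

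For the small nucleolar RNAs, one equal shift of all short RNAs against the control is argued against with miR-608 only. With copies of one RNA averaged in both classes, the spliceosomal median was 0.33 and theirs -0.321, which lie 0.651 apart (permutation test over 86 RNAs, p = 0.0087). Only 6 of these RNAs are spliceosomal, and as a family they did not pass with miR-608. With miR-552-3p the spliceosomal median lay 0.584 above theirs (permutation test over 86 RNAs, p = 0.023). That gap cannot decide, since both classes rose and the offset understates changes of dim probes. Of the small nucleolar RNAs, 85 had a mean not above that of the median row. Permutation p-values here take RNAs or probes as units and do not measure the spread between arrays. By probe, the spliceosomal medians were 0.101 and 0.397 on the miR-608 arrays and 1.2 and 1.14 on the miR-552-3p arrays. The small nucleolar medians on the same arrays were -0.353 and -0.314, and 0.389 and 0.347. Between the mimics both classes were lower with miR-608 and their medians lay 0.0258 apart (permutation test, p = 0.93), so a different recovery of short RNAs between the mimics, or one that depends on length, may be a cause and stays open. Signal from the mature transcripts of the genes that enclose them is argued against by 51 measured enclosing genes, with a median difference between the mimics of -0.106. Over 76 pairs, the median of small nucleolar RNA minus enclosing gene was -0.718. Signal from unspliced transcripts of those genes was not tested. Genes were paired by position without a check of strand or intron, and some enter several pairs, so not all are verified hosts. SNORA13, for example, lay within both EPB41L4A and EPB41L4A-AS1. Dim probes stay open, since only 11 small nucleolar RNAs had a mean above that of the median row and their median difference was -0.259 (permutation test over probes, p = 0.096). A split tried earlier, on detection on all arrays, gave -0.74 over 43, but a minimum in every array removes probes that fell, and an effect of the mimics' sequences was not tested.

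As a list, interferon-stimulated genes shifted up with miR-608 (10 of 19 higher; adjusted p = 0.147 with an estimated correlation) and down with miR-552-3p (8 of 19 lower; adjusted p = 0.25 with an estimated correlation), and the difference between the mimics had an adjusted p = 0.196 with an estimated correlation. Dim probes as the cause of the difference between the mimics are argued against by the 5 members with a mean above that of the median row, whose mean difference was 0.935 (permutation test over probes, p = 0.00061), though these are few and the p-value does not measure the spread between arrays. Background correction and normalization are argued against for that difference and for the shift with miR-608. Under the 5 other settings the difference was 0.668 to 0.984 (adjusted camera p at most 0.000299). The shift with miR-608 was 0.435 to 0.618 (adjusted camera p at most 0.000625), each with a preset correlation. The authors' values, no background correction and normexp keep the quantile step, so only cyclic loess and median scaling changed the normalization between arrays. Both causes stay open for the shift with miR-552-3p. It kept its direction (-0.411 to -0.232) but did not pass with the authors' values (adjusted p = 0.0586). An effect of each microRNA and a response of the cells to the particular RNA duplex, which may differ between mimics, are not separated by a design with 1 control mimic.

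Both mimics changed many genes in the same direction. Independent variation of the shared control arrays is argued against as the whole cause: the covariance of the fold changes was 0.07725 with a highest simulated value of 0.0138, and with a different control array for each mimic it was 0.05925 and 0.06129 with a highest simulated value of 0.00171. The correlation was 0.320 with shared controls, where unchanged groups gave 0.478 to 0.527 from noise alone. That comparison does not decide, since changes particular to 1 mimic lower the correlation. With different control arrays the correlation was 0.229 and 0.239, where unchanged groups gave -0.0262 to 0.0427. What remains may come from targets or downstream responses the microRNAs have in common, or from any active mimic against this control mimic. It may also come from a deviation common to both control arrays, which may come from 1 culture. The simulations hold no such deviation, and splitting the control arrays would not remove it. No test here separates these causes.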
